A study of Mus musculus with 32 samples.

How the data were processed

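Lung RNA from 16 male C57BL/6J mice, 6 to 8 weeks old per the labels, was measured in 4 groups of 4: control, WTCPM, WTCPM with rosoxacin (5 mg/kg) and WTCPM with dexamethasone (0.1 mg/kg). Total RNA was isolated with TRIzol and sequenced on an Illumina HiSeq instrument per the labels. Per the submitters' processing notes, the tools were FastQC, HISAT, HISAT2 2.2.1, SAMtools 1.12, StringTie 2.1.5 and R 4.0.4, and the genome build was mm10. The order and settings of these tools and the gene annotation are not given in the sources used here. The deposited values are FPKM per transcript, made by the authors, in 1 table of 32 libraries. The 32 files of single libraries hold the same values. The number of reads per library is not given in the sources used here, so the depth is unknown and the precision of a value could be judged from the mice alone.

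The 2 lanes of a mouse carry the same animal and library number in the labels and were averaged on the FPKM scale, so that n is the number of mice. FPKM of transcripts were summed per locus or gene identifier, which gave 54640 features. Features with a mean of at least 1 FPKM over the 16 mice were tested, 17355 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend) on log2(FPKM + 1), with all 4 groups in 1 fit and 6 comparisons, and a threshold of 0.05 on the Benjamini-Hochberg adjusted p. These choices, the naming rule, the gene lists and most alternatives were fixed before the data were examined.

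Because 99.89% of FPKM lies in loci without a gene name, the named genes and gene lists could not be run in that fit. This departs from the plan. They were run in a second fit, chosen after the files were seen, over the 2749 features with an Ensembl gene identifier and a mean of at least 0.1 FPKM, on log2(FPKM + 0.1). Symbols, coordinates, types and overlaps came from GENCODE M21 on mm10. Of 26305 Ensembl genes, 24950 matched an identifier of that release with its version and 25424 received a symbol. No locus was given a name.

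The naming rule took, for each of the first 3 comparisons, the 10 risen and 10 fallen genes with the largest log2 change among those past the threshold whose 4 mice of one group all lay above the 4 of the other. If fewer than 5 genes passed, it also took the 10 with the smallest unadjusted p, given as not passing. For the other 3 comparisons it took 5 and 5. Predicted genes and unnamed loci were counted and not named, and from each list up to 4 passing members, or else the 2 with the highest mean, were taken.

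There were 39 gene lists with 653 genes, of which 46 have an own identifier and 22 were tested, in 14 lists. The 2 lists with at least 3 tested genes, cytokines and chemokines, were tested with camera from limma at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The members of the other lists are not analysed here as sets. Lists of adipocyte genes, cell division genes and antigen receptor variable segments were added after the data were seen, and their results are in the closing section.

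The procedure was tested on simulated data with 200 changed features per comparison. Among loci, changes of 1 on the log2 scale were recovered in 79.1% of cases for WTCPM against control, 79.1% for rosoxacin against WTCPM and 83.6% for dexamethasone against WTCPM, and among annotated genes in 32.8%, 38.8% and 40.3%. Between 2.15% and 6.38% of the calls were false. The simulated noise was drawn independently for each feature, without the structure among mice described below. These rates may therefore not hold for the real data.

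For the relation of the drug effects to that of dust, 100 sets of unchanged groups sharing the same mice were simulated, and the WTCPM mice were split 2 and 2 in all 6 ways. Correlations across mice were tested with 100000 permutations. Alternatives tried were rescaling to TPM, median-of-ratios scaling, quantile normalisation, a pseudocount of 0.1, other filters, single lanes, all 32 libraries with the mouse as a random effect (statmod 1.5.0), transcripts, the most abundant transcript per locus, the 2 compared groups alone, no trend, array quality weights, a residual principal component as covariate, a replicate block, fold thresholds and each mouse left out. Added after the data were seen were the library number as a covariate, leaving out the mice with the highest totals, and leaving out the 10 most abundant loci. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A test of GC content and length is left out, because 31 of the 17355 features (0.179%) have such a value.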

Results

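Lung RNA of 16 male C57BL/6J mice was sequenced in 4 groups of 4 mice. One group was left unexposed (control). The other 3 were exposed to World Trade Center particulate matter (WTCPM), settled dust gathered near Ground Zero. Of these, one group received the dust alone, one also received rosoxacin, a quinolone antibiotic, at 5 mg/kg, and one also received dexamethasone, a synthetic glucocorticoid, at 0.1 mg/kg. Each mouse was sequenced on 2 lanes, which gave 32 libraries. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) for 186512 transcripts. Read counts per library are not given in the sources used here, so the depth is unknown and no limit of detection is stated. The FPKM of a mouse summed to between 704683 and 1329954. The group means of this total were 836634 ± 178146 in control, 770770 ± 31240 in WTCPM, 1066174 ± 183095 in rosoxacin and 803303 ± 44351 in dexamethasone mice (SD, n = 4 each). Between 25048 and 27232 loci or genes per mouse had an FPKM above 0.1.

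Features of 2 kinds carry these values. Assembled loci with an MSTRG identifier, the form StringTie gives to loci it assembles, numbered 28335 and held 99.89% of all FPKM, and the files do not pair them with gene names. Annotated genes with an Ensembl identifier numbered 26305, held 0.114% of all FPKM and had a highest mean of 4.05 FPKM. Most familiar lung genes therefore have no value under their own name, and which loci hold them is not given in the sources used here. The comparisons are first given for the 17355 features with a mean FPKM of at least 1, of which 17324 are assembled loci, and then for 2749 annotated genes with a mean of at least 0.1, whose names come from GENCODE. Values below are mean FPKM ± SD over the 4 mice of a group, and p-values are adjusted p-values from limma. Every gene or locus named as risen or fallen had all 4 mice of one group above all 4 of the other, because the rule for naming requires it. Unnamed loci are quoted by identifier for 2 that rose and 2 that fell, chosen after their values were seen. Others are given an identifier only for their abundance or for values close to these.

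The 2 lanes of a mouse gave nearly the same profile, with Pearson correlations of log2(FPKM + 1) across features of 0.980 to 0.990, against 0.910 to 0.990 between mice of the same group. The first principal component held 45.9% of the variance and set the rosoxacin mice, with scores of 34.1 to 48.8, apart from all others, which lay between -49.8 and 7.89. The same component followed the library number, which is the number after the letter S in each sample's label and whose meaning is not given in the sources used here. Rosoxacin mice carry the library numbers 1 to 4, WTCPM mice 5 to 17, control mice 7 to 23 and dexamethasone mice 9 to 22. Over the 12 mice outside the rosoxacin group the score fell with the library number, with Pearson r = -0.864 (permutation p = 0.00017) and Spearman rho = -0.923 (permutation p = 7e-05). The value of r was -0.804 over the 10 mice left without the 2 mice farthest from the median library number, and -0.845 after both measures were centred on the group means. This was the only such relation computed across mice. Rosoxacin treatment and the lowest library numbers coincide in every mouse, so these cannot be told apart by group.

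**Figure D1:**
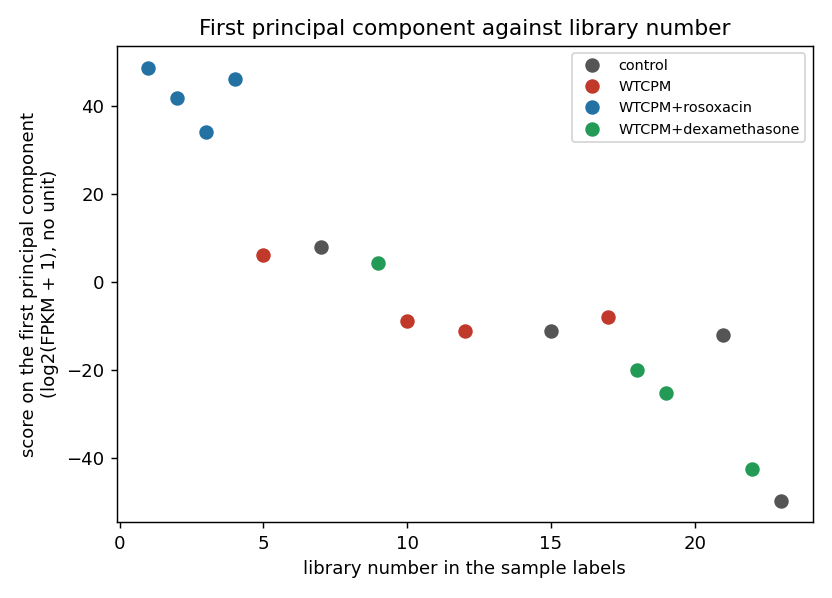
Score on the first principal component of log2(FPKM + 1) (y axis, no unit) against library number (x axis) for 16 mice, 1 point per mouse, coloured by group. The 4 rosoxacin mice lie at library numbers 1 to 4 with scores of 34.1 to 48.8, and the other 12 mice fall from 7.89 to -49.8 as the library number rises.

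The first comparison, WTCPM against control, asks which lung transcripts differ after exposure to the dust. One assembled locus, MSTRG.23017, rose from 1.21 FPKM in control (0.444 to 2.88 in single mice) to 47.7 ± 16.3 in WTCPM mice (n = 4 each), and its levels in rosoxacin mice (68.3 ± 39.2) and dexamethasone mice (50.4 ± 22.1) were in the same range. Another, MSTRG.23451, fell from 21.4 ± 17.6 to 3.05 ± 0.815 FPKM. The 3 genes given next had higher means after dust, but none passed the test over all annotated genes. Saa1, which encodes an acute-phase serum amyloid A protein, averaged 0.286 ± 0.0827 FPKM after dust against 0.0204 ± 0.0134 in control. Cxcl2, a chemokine that attracts neutrophils, averaged 0.534 ± 0.28 against 0.188 ± 0.102, and Osm, the cytokine oncostatin M, 0.553 ± 0.0948 against 0.316 ± 0.136.

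Of the 17355 features, 7 passed the threshold, 1 risen and 6 fallen. At an unadjusted p under 0.05, 871 features (5.02%) differed. MSTRG.23017 changed by 4.50 on the log2 scale (SE 0.46, adjusted p = 0.000455), and MSTRG.23451 fell by 2.22 (SE 0.35, adjusted p = 0.0233). The count of 7 became 12 without control 1 and 4 without control 3, without WTCPM 2 or without WTCPM 4. MSTRG.23451 no longer passed without control 3 (adjusted p = 0.0616), WTCPM 1 (0.084), WTCPM 2 (0.152), WTCPM 3 (0.0853) or WTCPM 4 (0.0603), over a range of 1.95e-05 to 0.152 across all settings, whereas MSTRG.23017 passed in each of 33 settings with adjusted p of at most 0.00743.

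Of the gene lists fixed before the data were examined, 2 had enough measured members for a set test. In the cytokine list all 3 measured members had higher means after dust, Osm, Il12b (0.254 ± 0.129 against 0.108 ± 0.0957, a subunit of interleukins 12 and 23) and Il11 (0.205 ± 0.0233 against 0.107 ± 0.0144). Their median change was 0.70 on the log2 scale, and limma's camera called the list up (adjusted p = 0.00355, and adjusted p = 0.0267 with an estimated correlation), as did fry (adjusted p = 0.0102). In the chemokine list 4 of 5 measured members had higher means, with a median change of 0.83. They were Cxcl2, Cxcl1 (0.36 ± 0.0788 against 0.289 ± 0.168), Cxcl5 (0.192 ± 0.0758 against 0.0673 ± 0.0539) and Ccl4 (0.212 ± 0.149 against 0.0724 ± 0.145), while Ccl20 was at 0.271 ± 0.0855 against 0.318 ± 0.0921. Camera called this list up (adjusted p = 0.00671), but adjusted p = 0.127 with an estimated correlation, 0.106 by fry and 0.0594 by camera without control 4. Il11, Cxcl5, Ccl4 and Ccl20 lie outside the rule for naming and were chosen after their values were seen. In each list 1 member passed when adjusted over the list alone, Osm (adjusted p = 0.033) and Cxcl2 (adjusted p = 0.0172), and 0 passed over all annotated genes by limma.

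**Figure D2:**
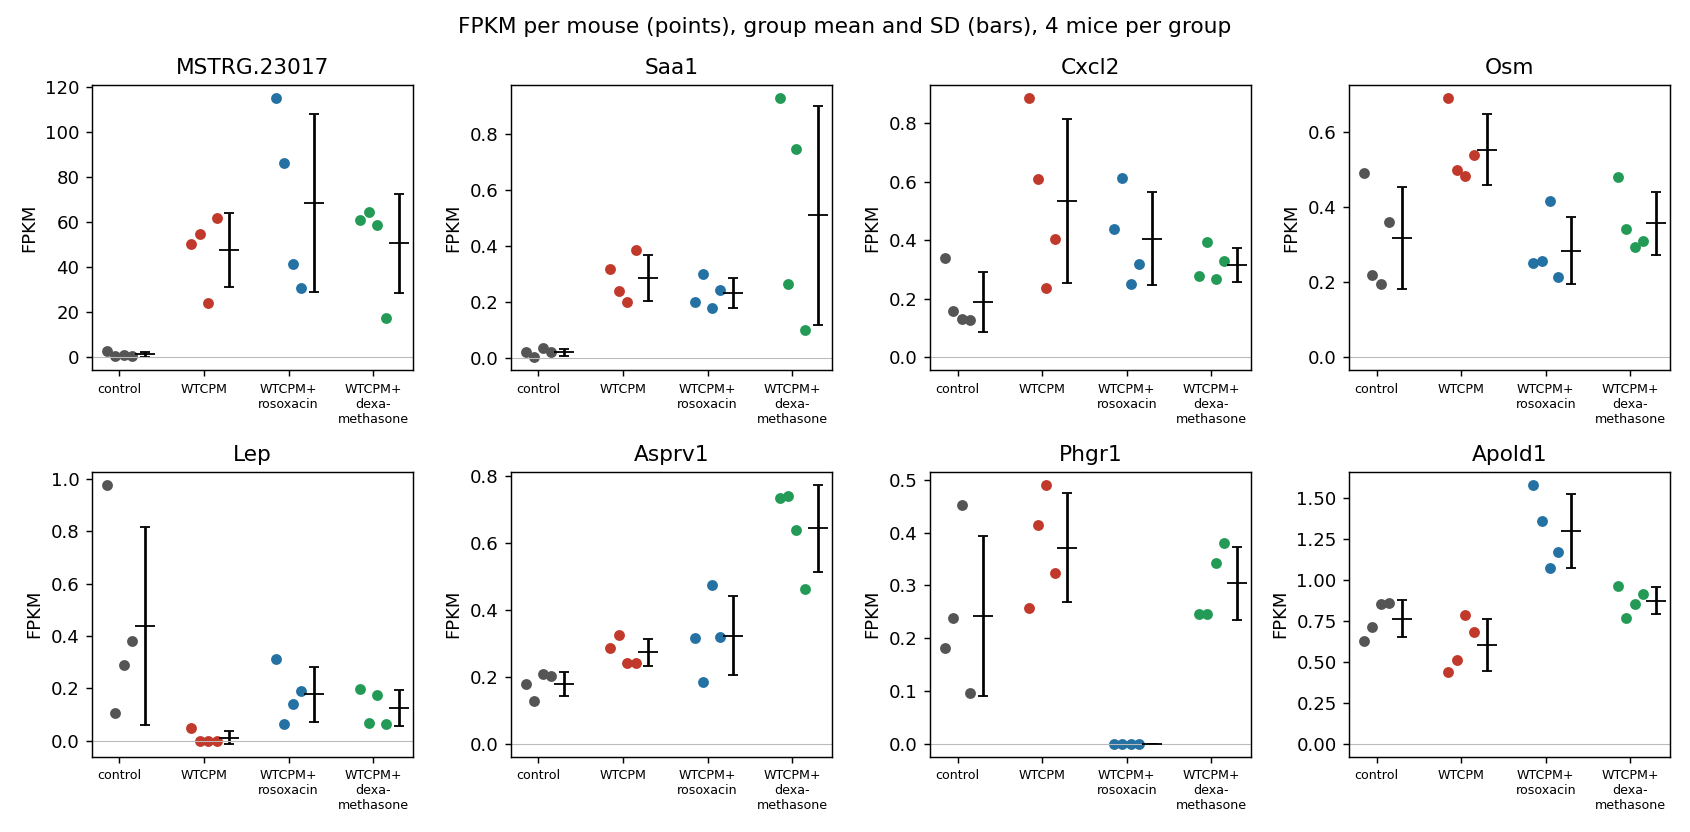
FPKM (y axes) of the locus MSTRG.23017 and of 7 annotated genes in the 4 groups (x axes), with 1 point per mouse and bars for the group mean and SD of 4 mice. MSTRG.23017 lies at 0.444 to 2.88 in control and at 17.5 to 115 in the 3 exposed groups, and Phgr1 is listed at 0 in all 4 rosoxacin mice.

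Over the 2749 annotated genes 0 passed limma's test for WTCPM against control, and 141 (5.13%) had an unadjusted p under 0.05. Genes from the 10 with the smallest p are given as not passing. Lep, the hormone leptin made by adipocytes (chromosome 6, 29060220 to 29073877), averaged 0.0118 ± 0.0235 FPKM after dust against 0.438 ± 0.378 in control (log2 change -2.03, SE 0.42, adjusted p = 0.131). Lep passed without control 2 (adjusted p = 0.038), within a range of 0.038 to 0.386 over the fits that leave out 1 mouse. Hcar1, a lactate receptor of adipocytes, averaged 0.1 ± 0.0277 against 0.447 ± 0.326, and Tmem179 0.084 ± 0.0438 against 0.445 ± 0.331 (adjusted p = 0.324 for each). Control 1 raised these control means, with Lep at 0.978 (other controls 0.105 to 0.381), Hcar1 at 0.917 (0.197 to 0.41) and Tmem179 at 0.916 (0.154 to 0.405). Of antigen receptor variable segments, Ighv1-50 averaged 0.0637 ± 0.0758 against 0.676 ± 0.497 and Trbv1 0.156 ± 0.109 against 0.628 ± 0.189. Trdv2-2 was listed at 0 in the 4 WTCPM mice against 0.352 ± 0.161 in control (adjusted p = 0.131). Higher after dust were Saa1 (chromosome 7, 46740497 to 46742980; log2 change 1.66, SE 0.39, adjusted p = 0.265), Rxfp4 (0.629 ± 0.181 against 0.26 ± 0.0923) and Prr11 (0.414 ± 0.108 against 0.176 ± 0.0707), the last 2 with adjusted p = 0.324. Variable segments and Saa1 have near-identical relatives whose reads the counting could have shared, so their values are uncertain.

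Of the other lists, 12 had only 1 or 2 measured members, so that adjusting over the list changes p little or not at all. Adjusted over the list alone, Lep (adipocyte markers, adjusted p = 0.000146), Saa1 (NF-kB targets and acute phase, adjusted p = 0.000481), C3ar1, the receptor of complement fragment C3a (adjusted p = 0.0285), and Xcr1, a receptor of cross-presenting dendritic cells (adjusted p = 0.03), passed for WTCPM against control, and 0 passed over all annotated genes by limma. C3ar1 averaged 1.13 ± 0.134 against 0.866 ± 0.105 FPKM and Xcr1 0.589 ± 0.0488 against 0.405 ± 0.0364. The members measured for neutrophils (Cxcr2, log2 change 0.04), eosinophils, basophils and mast cells (Gata1 0.24, Il5ra -0.70), club and goblet cells (Spdef -0.07), endothelium (Prox1 0.50), pattern recognition (Tlr9 -0.04, Tlr6 0.12), metal response (Slc30a2 -0.31), p53 response (Gdf15 0.09) and matrix metalloproteinases (Mmp13 -0.04) did not pass either way. The sign for Cxcr2, Spdef, Tlr9, Tlr6, Gdf15 and Mmp13 differed in at least 1 alternative setting or fit without 1 mouse.

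The second comparison, rosoxacin with dust against dust alone, asks what the drug does in exposed lungs. The locus MSTRG.17929 rose from 42.5 ± 15.3 to 566 ± 108 FPKM (n = 4 each), against 40.6 ± 15.5 in control, and MSTRG.5629 fell from 234 ± 71.3 to 74.1 ± 33.7. A further locus, MSTRG.17927, had nearly the same means as MSTRG.17929 (42.3 and 563 FPKM). Whether these loci share reads was not tested, so they may not be separate results. Itln1, a secreted lectin that binds microbial glycans (chromosome 1, 171518122 to 171535294), rose from 0.0146 ± 0.0292 to 0.411 ± 0.211, and Apold1, a gene of the vascular endothelium (chromosome 6, 134981718 to 134986836), from 0.603 ± 0.158 to 1.29 ± 0.223. Phgr1 (chromosome 2, 118772769 to 118778165) fell from 0.371 ± 0.103 to a level listed at 0 in all 4 rosoxacin mice, and the long noncoding RNA Eprn (chromosome 13, 73344665 to 73347384) from 0.345 ± 0.143 to 0.00929 ± 0.0186. Tmem52 fell from 0.262 ± 0.148 to a level listed at 0 in all 4 mice, Pcdh20, a protocadherin, from 0.569 ± 0.112 to 0.153 ± 0.0749, and Kbtbd13 from 0.525 ± 0.121 to 0.171 ± 0.0354.

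Of the 17355 features, 5940 passed, 662 risen and 5278 fallen (88.9%). The most abundant loci, MSTRG.5637 and MSTRG.5630, held 23.4% and 19.9% of all FPKM. They averaged 168000 and 141000 FPKM in WTCPM against 292000 and 241000 in rosoxacin mice (adjusted p = 0.157 and 0.149 by limma). The 10 most abundant loci held 57.4 ± 1.88% of FPKM in WTCPM and 63.6 ± 3.97% in rosoxacin mice. Changes in the rosoxacin group are also given relative to the median of all features. That median was -0.22 on the log2 scale as deposited, 0.01 after median-of-ratios scaling, -0.03 after quantile normalisation and -0.58 after rescaling to TPM. A relative change is the deposited change minus the median and not the result of a rescaling. With median-of-ratios scaling 3286 features passed, 1752 risen and 1534 fallen, and with quantile normalisation 3948 passed, 1799 risen and 2149 fallen. Relative to the median, MSTRG.17929 changed by 3.96 (3.74 as deposited, SE 0.32, adjusted p = 5.15e-06) and MSTRG.5629 by -1.50 (-1.72 as deposited, SE 0.29, adjusted p = 0.000593). Both passed in each of 33 settings, but the size for MSTRG.5629 depended on the setting, with log2 changes from -4.51 to -1.38. For MSTRG.17929 they ranged from 3.3 to 4.03. With the library number as a covariate, added after the data were seen, 4623 features passed, 369 risen and 4254 fallen.

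**Figure D3:**
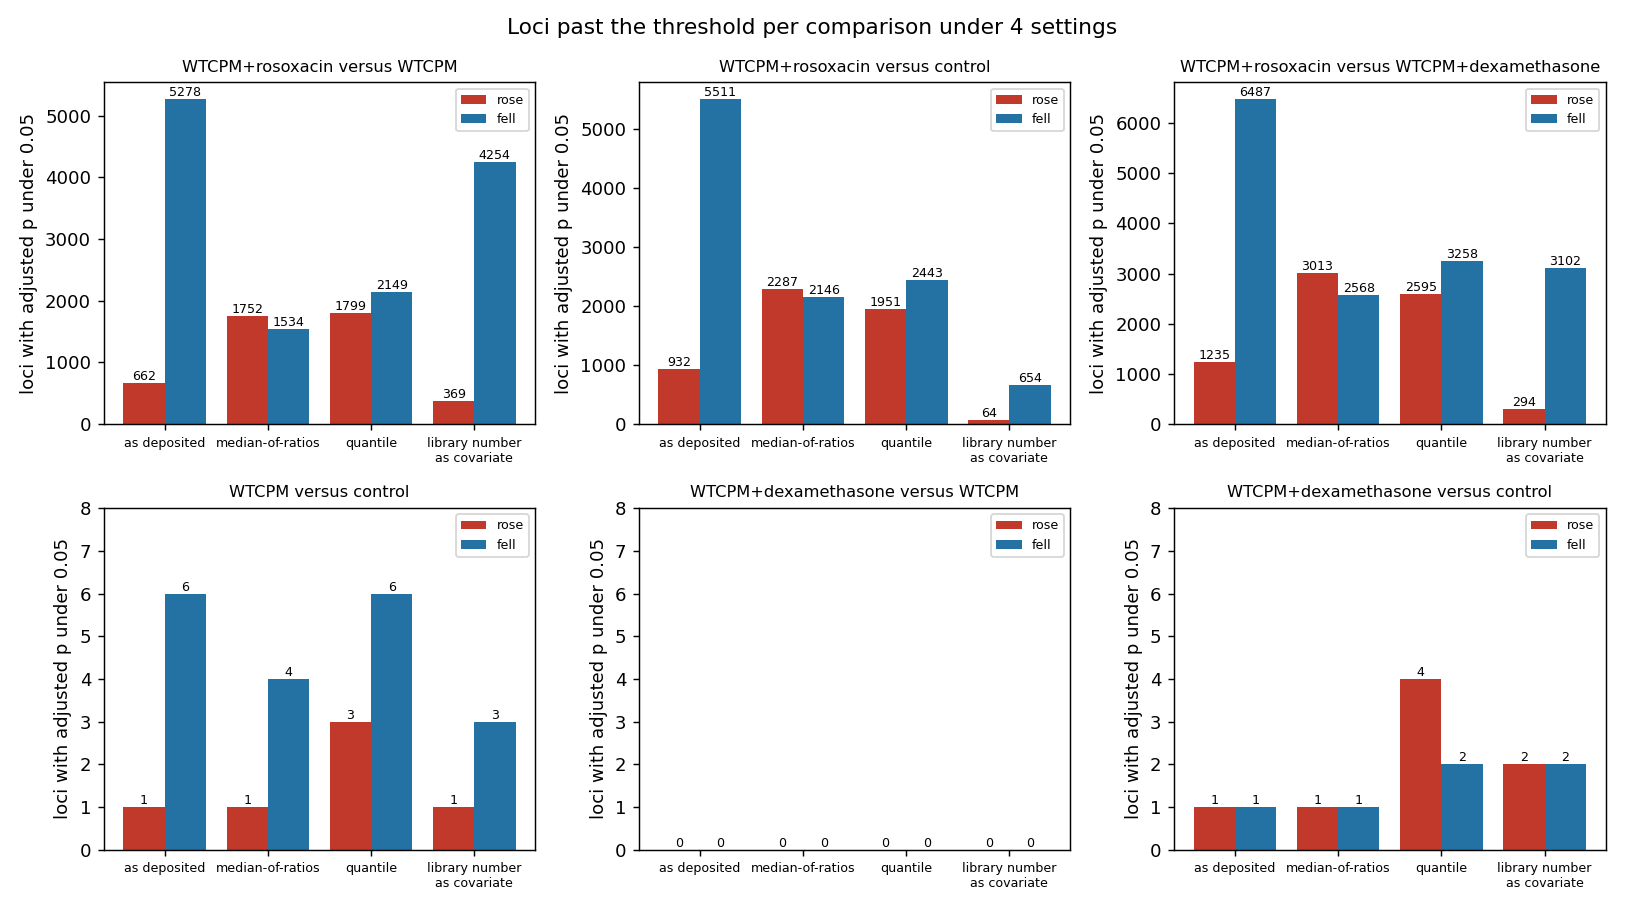
Number of features past the threshold (y axes), risen and fallen as separate bars, in the 6 comparisons (panels) under 4 settings (x axes): as deposited, median-of-ratios scaling, quantile normalisation, and library number as a covariate. For rosoxacin against WTCPM the bars run from 662 risen and 5278 fallen as deposited to 1752 risen and 1534 fallen with median-of-ratios scaling.

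Over the annotated genes 15 passed for rosoxacin against WTCPM, 3 risen and 12 fallen, and the median of all annotated genes was -0.16. Relative to this median the log2 changes were 2.24 for Itln1 (adjusted p = 0.0401), 1.16 for Apold1 (0.0176), -1.80 for Eprn (0.00152), -1.29 for Pcdh20 (0.0148) and -1.03 for Kbtbd13 (0.0184). Adjusted p was 0.00113 for Phgr1 and 0.0176 for Tmem52. All these adjusted p-values are for the changes as deposited, and the relative changes were not tested. Normalised fits can differ from them: with quantile normalisation the log2 change was 2.07 for Itln1, 1.01 for Apold1 and -1.13 for Kbtbd13. With median-of-ratios scaling Kbtbd13 did not pass limma's test (adjusted p = 0.0584). Phgr1 and Eprn passed in every setting and without any 1 mouse, with adjusted p of at most 0.0244 and 0.0295. The other 5 did not pass with the library number as a covariate, at adjusted p of 0.0948 for Itln1, 0.0787 for Apold1, 0.0948 for Tmem52, 0.0787 for Pcdh20 and 0.111 for Kbtbd13, and their ranges over all 5 alternative settings, this one included, were 0.0225 to 0.0948, 0.00455 to 0.0981, 0.0219 to 0.126, 0.0155 to 0.0787 and 0.0408 to 0.144. Pcdh20 passed in each of the other alternatives. With the covariate the log2 changes themselves were 2.16 for Itln1 (2.08 without it), 1.00 for Apold1 (1.00), -1.39 for Pcdh20 (-1.45) and -0.88 for Kbtbd13 (-1.19). Itln1 was past the threshold no longer without control 2 (adjusted p = 0.0555), control 3 (0.054), WTCPM 1 (0.0707), WTCPM 2 (0.106), WTCPM 3 (0.0943), WTCPM 4 (0.0643), rosoxacin 1 (0.0996), rosoxacin 3 (0.126) or rosoxacin 4 (0.103). Apold1 was lost without WTCPM 2 (0.0784), WTCPM 4 (0.0582) or rosoxacin 1 (0.0653), Tmem52 without WTCPM 3 (0.0514), WTCPM 4 (0.0643) or rosoxacin 1 (0.0653), and Pcdh20 without WTCPM 4 (0.0626). Kbtbd13 was lost without WTCPM 2 (0.0784), WTCPM 3 (0.0514), WTCPM 4 (0.0643), rosoxacin 1 (0.0661) or rosoxacin 3 (0.0513).

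Osm averaged 0.284 ± 0.0899 FPKM with rosoxacin against 0.553 ± 0.0948 with dust alone. The median of the 3 cytokines was -0.39 and camera did not call the list (adjusted p = 0.447, and 0.0794 by fry). For the 5 chemokines the median, -0.19, and camera's direction, up, differed in sign (adjusted p = 0.691). Adjusted over the list alone, Osm (adjusted p = 0.0152), Xcr1 (adjusted p = 0.0074), Lep (adjusted p = 0.00826), Mmp13, a collagenase (adjusted p = 0.0401), and Gata1, a transcription factor of the erythroid, mast cell and eosinophil lineages (adjusted p = 0.0438), passed in their lists, and 0 of them passed over all annotated genes by limma. Xcr1 averaged 0.367 ± 0.0769, Lep 0.176 ± 0.104, Mmp13 0.101 ± 0.0686 and Gata1 0.0806 ± 0.0972 with rosoxacin, against 0.589 ± 0.0488, 0.0118 ± 0.0235, 0.21 ± 0.0599 and 0.202 ± 0.0375 with dust alone. These p-values are for changes as deposited and were not computed relative to the median, where the changes are smaller for Osm (-0.62 instead of -0.78), Xcr1 (-0.41 instead of -0.57), Mmp13 (-0.50 instead of -0.66, SE 0.30) and Gata1 (-0.74 instead of -0.90, SE 0.36). Whether the 4 calls hold relative to the median was not tested. Of all 2749 annotated genes 431 (15.7%) had an unadjusted p under 0.05 by limma. Whether passes in lists this short exceed that share was not tested.

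The third comparison, dexamethasone with dust against dust alone, asks what the glucocorticoid does in exposed lungs. The 3 measured cytokines had lower means with dexamethasone, Osm at 0.356 ± 0.0846 against 0.553 ± 0.0948 FPKM, Il12b at 0.104 ± 0.156 against 0.254 ± 0.129 and Il11 at 0.138 ± 0.0764 against 0.205 ± 0.0233 (n = 4 each). Camera called the list down, with a median of -0.53 on the log2 scale (adjusted p = 0.0061, and adjusted p = 0.0353 with an estimated correlation), as did fry (adjusted p = 0.0233), and the call was lost without dexamethasone 4 (adjusted p = 0.0988). Cxcr2, the chemokine receptor of neutrophils (chromosome 1, 74153989 to 74161246), averaged 1.13 ± 0.344 against 0.516 ± 0.107. The chemokines as a list were not called (adjusted p = 0.932), with a median of 0.03 and a camera direction of down, so that the signs differed.

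Of the 17355 features 0 passed limma's test, with a smallest adjusted p of 0.135 and 925 (5.33%) at an unadjusted p under 0.05, and 0 passed without any 1 mouse. Of the 2749 annotated genes 0 passed, with 148 (5.38%) at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, included Asprv1, a skin aspartic protease (chromosome 6, 86628164 to 86629710), at 0.644 ± 0.131 against 0.273 ± 0.0404 (log2 change 0.98, SE 0.23, adjusted p = 0.391). Cxcr2 (0.97, SE 0.30), Rdh12, a retinol dehydrogenase (0.96, SE 0.29), and Zfp786 (-0.66, SE 0.20) had an adjusted p of 0.631, as did Inpp5j (-1.02, SE 0.31) and the pseudogene Rps7-ps1 (1.11, SE 0.34). Tdrd5 (-0.94, SE 0.23, adjusted p = 0.486), Shd (-1.15, SE 0.32, adjusted p = 0.575), the pseudogene Rpl31-ps1 (0.76, SE 0.24, adjusted p = 0.68) and Slc14a1, a urea transporter (0.67, SE 0.23, adjusted p = 0.861), completed the 10. Tdrd5 overlaps A430050A11Rik on the same strand and Inpp5j overlaps Pla2g3 on the other, so their values, like those of the pseudogenes, are uncertain. Adjusted over the list alone, Cxcr2 (adjusted p = 0.00452) and Lep (adjusted p = 0.0322) passed in their lists, and 0 passed over all annotated genes by limma. The usual glucocorticoid readouts Fkbp5, Tsc22d3, Per1 and Zbtb16 have no value under their own identifier and are not analysed here.

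Whether a drug turned back the changes after dust was examined by setting the fold changes of dust against those of each drug, across loci, which are not independent replicates. The WTCPM mice enter both contrasts with opposite sign, so that a negative correlation arises by chance. For dexamethasone the correlation was r = -0.563, where 100 simulated sets of unchanged groups gave -0.424 ± 0.32 (SD). With different WTCPM mice in the contrasts, averaged over 6 splits, it was -0.27 ± 0.0739. Here ± is the SD over overlapping splits of the same mice and not an error of r. The covariance was -0.0238 against -0.0151 ± 0.0174 in the simulated sets, and 68.5% of loci had opposite signs against 64.7%. For rosoxacin r was -0.0056 against -0.472 ± 0.253, and 0.0873 ± 0.121 over the 6 splits. Its covariance was -0.000471 against -0.0167 ± 0.0149, with opposite signs at 53.1% of loci against 66.2%. Of the 7 features called after dust, 7 had the opposite sign with dexamethasone and 6 with rosoxacin, where 1 was also called. These 7 were selected with the same WTCPM mice that enter the drug contrasts, which favours opposite signs. The simulated shares are for all loci and not for called ones, so these counts cannot show a reversal. MSTRG.23017 stayed at 50.4 ± 22.1 FPKM with dexamethasone and 68.3 ± 39.2 with rosoxacin, against 47.7 ± 16.3 with dust alone. The fold changes of the 2 drugs against dust alone correlated at r = -0.267, where simulated unchanged groups gave 0.44 ± 0.279, and at -0.331 ± 0.105 over the 6 splits. Their covariance was -0.0203 against 0.0154 ± 0.0143. Splitting the WTCPM mice does not remove the library number, with a mean of 16.5 in control, 11 in WTCPM, 2.5 in rosoxacin and 17 in dexamethasone mice. A gradient with that number could also give opposite signs for dust and dexamethasone, and for the 2 drugs. The correlations cannot tell this from an effect of the drugs. No shared calls could arise, since dexamethasone against WTCPM gave 0.

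The fourth comparison, rosoxacin with dust against control, asks whether treated exposed lungs still differ from unexposed ones. MSTRG.23017 rose from 1.21 (0.444 to 2.88) to 68.3 ± 39.2 FPKM (5.07 relative to the median of all features, 4.89 as deposited, adjusted p = 1.33e-05). Saa1 rose from 0.0204 ± 0.0134 to 0.231 ± 0.0523 (n = 4 each), P4ha3, a subunit of collagen prolyl 4-hydroxylase, from 0.134 ± 0.0527 to 0.432 ± 0.0966, Fam163b from 0.378 ± 0.124 to 1.2 ± 0.494, and the kinase gene Hipk4 from 0.364 ± 0.116 to 0.805 ± 0.198. Itln1 rose to 0.411 ± 0.211 from a level listed at 0 in all 4 control mice. Trbv16, Trbv3, Trdv2-2 and Cd164l2 fell from 0.54 ± 0.456, 0.605 ± 0.505, 0.352 ± 0.161 and 0.344 ± 0.0907 to levels listed at 0 in all 4 rosoxacin mice, and Ighv1-19 fell from 0.985 ± 0.8 to 0.0645 ± 0.129.

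Of the 17355 features 6443 passed for rosoxacin against control, 932 risen and 5511 fallen (85.5%), with a median of -0.18 as deposited and 0.02 with median-of-ratios scaling. Median-of-ratios scaling gave 4433 (2287 risen and 2146 fallen), quantile normalisation 4394 (1951 risen and 2443 fallen), and the library number as a covariate 718 (64 risen and 654 fallen). Over the annotated genes 91 passed, 18 risen and 73 fallen, with a median of -0.11. Relative to it, Saa1 changed by 1.56 (adjusted p = 0.0496), Fam163b by 1.51 (0.0315), P4ha3 by 1.31 (0.0315), Hipk4 by 1.09 (0.0414) and Ighv1-19 by -2.62 (0.0331). Adjusted p was 0.0217 for Itln1, 0.0312 for Trbv3 and 0.0219 each for Trbv16, Cd164l2 and Trdv2-2. These adjusted p-values are again for the changes as deposited and not for the relative ones. With quantile normalisation the log2 change was 1.43 for Saa1, 1.15 for P4ha3, 0.861 for Hipk4 and -2.73 for Ighv1-19. With median-of-ratios scaling Ighv1-19 did not pass limma's test (adjusted p = 0.0521). Cd164l2 overlaps Gpr3 on the other strand and is uncertain, as are the variable segments. None of these 10 genes passed with the library number as a covariate, at adjusted p of 0.282 (Itln1, Saa1, Trdv2-2) to 0.672 (Hipk4), the highest of all settings, where the lowest ranged from 0.0127 (Itln1) to 0.0418 (Ighv1-19). With the covariate the log2 change was 1.96 for Saa1 (1.45 without it), 1.24 for P4ha3 (1.20), -2.19 for Ighv1-19 (-2.73), 0.72 for Fam163b (1.40) and 0.44 for Hipk4 (0.98), and none is given for genes listed at 0 in a group.

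Each of these calls for rosoxacin against control was also lost when single mice were left out. Without control 1 the adjusted p was 0.0541 for Itln1, 0.11 for Saa1, 0.103 for Fam163b, 0.0937 for P4ha3, 0.115 for Hipk4, 0.11 for Ighv1-19, 0.103 for Trbv3, 0.0772 for Trbv16, and 0.0755 for Cd164l2 and Trdv2-2. Without control 2 it was 0.0898 for Saa1 and 0.069 for Hipk4. Without control 3 it was 0.0845 for Saa1, 0.0576 for Fam163b, 0.0664 for P4ha3, 0.0549 for Hipk4, 0.0571 for Ighv1-19, 0.0536 for Cd164l2 and 0.0571 for Trdv2-2. Without control 4 it was 0.0748 for Saa1, 0.0538 for Fam163b, 0.0599 for P4ha3, 0.0557 for Hipk4, 0.0575 for Ighv1-19, 0.0585 for Trbv3 and 0.0557 for Trdv2-2. Without rosoxacin 1 it was 0.0863 for Saa1, 0.0574 for P4ha3, 0.0594 for Hipk4, 0.0796 for Ighv1-19 and 0.0636 for Trbv3. Leaving out rosoxacin 2 gave 0.1 for Saa1, 0.0621 for Fam163b, 0.0698 for P4ha3, 0.0621 for Hipk4, 0.0682 for Ighv1-19 and 0.0606 for Trbv3. Leaving out rosoxacin 3 gave 0.0629 for Itln1, Trbv16, Cd164l2 and Trdv2-2, 0.0782 for Saa1, 0.0692 for Fam163b and Trbv3, 0.068 for P4ha3, 0.0761 for Hipk4 and 0.0774 for Ighv1-19. Leaving out rosoxacin 4 gave 0.0547 for Itln1, 0.0975 for Saa1, 0.0851 for Fam163b, 0.0679 for P4ha3 and Trbv3, 0.107 for Hipk4 and 0.05 for Trbv16. Saa1 was also lost without WTCPM 1 (0.0607), WTCPM 2 (0.0597), WTCPM 3 (0.0603), WTCPM 4 (0.0597), dexamethasone 2 (0.0573) or dexamethasone 3 (0.0521), and Hipk4 without WTCPM 4 (0.0516) or dexamethasone 3 (0.0542).

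The chemokine list had a median of 0.77 against control and was called up by camera (adjusted p = 0.0354), but adjusted p = 0.302 with an estimated correlation. The cytokine list was not called (adjusted p = 0.245). Adjusted over the list alone, Saa1 (adjusted p = 0.00156), Cxcr2 (adjusted p = 0.0496) and Mmp13 (adjusted p = 0.0312) passed in their lists, and of these Saa1 passed over all annotated genes by limma. At an unadjusted p under 0.05, 531 of the 2749 annotated genes (19.3%) differed, and whether the list passes exceed that share was not tested.

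The fifth comparison, dexamethasone with dust against control, asks the same of the glucocorticoid. MSTRG.23017 rose to 50.4 ± 22.1 FPKM from 1.21 (0.444 to 2.88) in control (log2 change 4.49, SE 0.46, adjusted p = 0.000458). Asprv1 rose from 0.179 ± 0.0362 to 0.644 ± 0.131 (n = 4 each). All 5 measured chemokines had higher means than in control, with a median of 0.58, among them Cxcl2 at 0.316 ± 0.0579 against 0.188 ± 0.102, and camera called the list up (adjusted p = 0.0073) but not with an estimated correlation (adjusted p = 0.209 with an estimated correlation). The cytokine list was not called (adjusted p = 0.727).

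Of the 17355 features 2 passed, 1 risen and 1 fallen, and 1191 (6.86%) had an unadjusted p under 0.05. The count became 9 without dexamethasone 4, 8 without rosoxacin 1 and 4 without rosoxacin 2. The unnamed fallen locus went from 20 ± 5.58 to 6.43 ± 1 FPKM (log2 change -1.47, SE 0.19, adjusted p = 0.00567). Over the annotated genes 1 passed, Asprv1 (log2 change 1.41, SE 0.23, adjusted p = 0.0247), with 137 at an unadjusted p under 0.05. Asprv1 was lost without control 2 (adjusted p = 0.164), control 3 (0.0695), control 4 (0.0698), dexamethasone 1 (0.161), dexamethasone 2 (0.1) or dexamethasone 3 (0.126), with median-of-ratios scaling (0.0565) and with quantile normalisation (0.117), over a range of 0.0171 to 0.117 across settings. Adjusted over the list alone, Saa1 (adjusted p = 5.34e-05), Cxcr2 (adjusted p = 0.00337) and Lep (adjusted p = 0.0215) passed in their lists, and 0 of them passed over all annotated genes by limma.

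The sixth comparison sets the drug groups against each other. Rosoxacin mice had more Fut2, a fucosyltransferase (1.06 ± 0.118 against 0.46 ± 0.0829 FPKM, n = 4 each), Hipk4 (0.805 ± 0.198 against 0.3 ± 0.0867), Ttll8, a tubulin glycylase (0.377 ± 0.0531 against 0.0915 ± 0.109), Mex3a, an RNA-binding protein (0.355 ± 0.0514 against 0.152 ± 0.044), and Slc1a7, a glutamate transporter (0.291 ± 0.0477 against 0.11 ± 0.0636). They had less Eprn, at 0.00929 ± 0.0186 against 0.431 ± 0.0925. Phgr1, Tmem52, Trbv16 and Igkv13-84 were listed at 0 in all 4 rosoxacin mice, against 0.304 ± 0.0684, 0.365 ± 0.177, 0.432 ± 0.248 and 0.612 ± 0.324 in dexamethasone mice. MSTRG.17929 stood at 566 ± 108 FPKM with rosoxacin and 26.7 ± 16.1 with dexamethasone.

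Of the 17355 features 7722 differed, 1235 higher and 6487 lower with rosoxacin (84%), with a median of -0.24 as deposited and 0.01 with median-of-ratios scaling. Median-of-ratios scaling gave 5581 (3013 higher and 2568 lower), quantile normalisation 5853 (2595 higher and 3258 lower), and the library number as a covariate 3396 (294 higher and 3102 lower). Over the annotated genes 117 differed, 15 higher and 102 lower. Relative to their median of -0.14, the log2 change was 1.65 for Ttll8 (adjusted p = 0.0434), 1.32 for Hipk4 (0.0226), 1.21 for Fut2 (0.0468), 1.08 for Slc1a7 (0.0386), 1.00 for Mex3a (0.032) and -2.13 for Eprn (0.000411). Adjusted p was 0.00215 for Phgr1, 0.00546 for Tmem52, 0.0299 for Trbv16 and 0.0468 for Igkv13-84. Here too the adjusted p-values are for the changes as deposited and not for the relative ones. With quantile normalisation the log2 change was 0.973 for Slc1a7 and 0.823 for Mex3a. With median-of-ratios scaling Igkv13-84 did not pass limma's test (adjusted p = 0.0712). None of the 10 passed with the library number as a covariate, at adjusted p of 0.108 (Eprn), 0.152 (Phgr1), 0.197 (Tmem52) and 0.277 (Mex3a) to 0.808 (Ttll8), the highest of all settings, where the lowest ranged from 0.000332 (Eprn) to 0.0558 (Igkv13-84). With the covariate the log2 change was -2.28 for Eprn (-2.28 without it), 0.94 for Mex3a (0.86), 0.93 for Slc1a7 (0.94), 0.63 for Hipk4 (1.18), 0.63 for Fut2 (1.06) and 0.34 for Ttll8 (1.5). Ttll8 overlaps AC117700.1 on the same strand and is uncertain.

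Eprn, Phgr1 and Tmem52 passed between the drug groups without any 1 mouse, with adjusted p of at most 0.0247. Without dexamethasone 1 the adjusted p was 0.151 for Ttll8 and Fut2, 0.081 for Hipk4 and Slc1a7, 0.0997 for Mex3a, 0.121 for Igkv13-84 and 0.0579 for Trbv16. Without dexamethasone 2 it was 0.0995 for Fut2, 0.0886 for Igkv13-84 and 0.0852 for Trbv16. Without dexamethasone 3 it was 0.109 for Ttll8, 0.0585 for Hipk4 and Trbv16, 0.0807 for Fut2, 0.101 for Slc1a7, 0.0752 for Mex3a and 0.0839 for Igkv13-84, and without dexamethasone 4 it was 0.0538 for Slc1a7 and 0.0804 for Igkv13-84. With rosoxacin 1 left out it was 0.0783 for Ttll8, 0.072 for Fut2, 0.0768 for Slc1a7, 0.0514 for Mex3a, 0.0837 for Igkv13-84 and 0.0579 for Trbv16. With rosoxacin 2 left out it was 0.0583 for Ttll8, 0.0814 for Fut2, 0.0502 for Slc1a7, 0.0605 for Mex3a and 0.0767 for Igkv13-84. With rosoxacin 3 left out it was 0.0816 for Ttll8, 0.052 for Hipk4, 0.0832 for Fut2, 0.0673 for Slc1a7, 0.0612 for Mex3a and Trbv16 and 0.0849 for Igkv13-84. With rosoxacin 4 left out it was 0.0913 for Ttll8 and Slc1a7, 0.0551 for Hipk4, 0.0999 for Fut2, 0.072 for Mex3a, 0.0848 for Igkv13-84 and 0.0587 for Trbv16. Fut2 was also lost without control 2 (0.0549), control 4 (0.0502), WTCPM 1 (0.0537), WTCPM 2 (0.0559) or WTCPM 3 (0.0538), Ttll8 without WTCPM 2 (0.0534) or WTCPM 3 (0.0522), and Igkv13-84 without WTCPM 2 (0.0534) or WTCPM 3 (0.0538).

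Neither the cytokine nor the chemokine list was called between the drug groups (adjusted p = 0.682 for each), although the chemokine median of -0.25 and camera's direction, up, differed in sign. Adjusted over the list alone, Gata1 (adjusted p = 0.00783) and the pattern recognition receptors Tlr9 and Tlr6 (adjusted p = 0.0217 each) passed in their lists, with Gata1 lower and Tlr9 higher in rosoxacin mice, and 0 of the 3 passed over all annotated genes by limma. Tlr9 averaged 0.941 ± 0.142 against 0.623 ± 0.139 FPKM and Tlr6 0.428 ± 0.0692 against 0.621 ± 0.0606. At an unadjusted p under 0.05, 568 of the 2749 annotated genes (20.7%) differed by limma, and whether the list passes exceed that share was not tested.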

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

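The tests of a linear gradient as the whole cause, of the 10 most abundant loci, of 1 scaling factor, of a step at the lowest library numbers, of variable segments, of splits for annotated genes and of splits for the cytokine and chemokine lists were chosen only after the result was seen.

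Many loci (5940 against WTCPM) differ between rosoxacin mice and every other group, and these mice hold the lowest library numbers. A gradient with library number may contribute, since across loci the slope in control and dexamethasone mice correlated with the change at r = -0.387. A linear trend is not enough against WTCPM, with 4623 loci still called with the covariate, but the covariate took the count against control from 6443 to 718 and against dexamethasone from 7722 to 3396, so a larger part there stays open. A single scaling factor per library does not account for the calls, with 3286 loci called with median-of-ratios scaling, which centres the changes by construction. Without the 10 most abundant loci 96% of calls fell. That fit rescaled the rest to a fixed sum, in which MSTRG.4897 remained (3440 FPKM in WTCPM, 28800 with rosoxacin). Rescaling all loci to TPM likewise gave a median of -0.58. Whether abundant loci lowered the FPKM of the others therefore stays open. A step at the lowest library numbers remains open, because 0 mice outside the rosoxacin group have so low a number, and so the drug and a batch cannot be separated.

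Of 7 features called after dust 6 fell, and adipocyte genes had lower means. Adipose tissue in the control samples may contribute: the added adipocyte genes that had not been seen before had a median of -0.53 after dust, 4 of 4 lower (camera p = 0.00745 with an estimated correlation, from limma), and of -0.55 with rosoxacin and -0.50 with dexamethasone against the same control mice. They are 4 genes with means of at most 0.585 FPKM in control, and less adipocyte RNA after dust would give the same values, so this is left open. A single control library is not the source, since 10 loci fell without control 1.

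The 35 splits of 8 mice into 4 and 4 were each fitted, the real one included. For WTCPM against control only the real split gave as many features (7, highest other 0). The same held for rosoxacin against WTCPM (5940, highest other 1), against control (6443, highest other 1010) and against dexamethasone (7722, highest other 56). A share of 1 in 35 is the smallest these splits can show, and several such tests were run. Mixed splits also add any group difference to the spread, which lowers their counts. Chance is therefore less likely for these comparisons but not excluded. For dexamethasone against control 2 splits gave as many (2, highest other 1098), so chance cannot be excluded there either. For dexamethasone against WTCPM the count is 0 by limma (925 at an unadjusted p under 0.05, highest other 0), which all 35 splits reach by construction, so the splits say nothing about it. The split with 1098 sets control 1 and dexamethasone 1 to 3, with a mean library number of 20.5, against the rest, with 13, and the split with 1010 sets control 1 and rosoxacin 1, 3 and 4 (7.5) against the rest (11.5). Splits that call so many features point to a structure of the samples. Its relation to the library number stays open: 3709 loci had a slope on that number past the threshold in these 8 mice, while the split of control 1, control 2, dexamethasone 1 and dexamethasone 3 (21.2 against 12.2) called 0 features by limma. With that number as a covariate dexamethasone against control gave 4.

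Among annotated genes only the real split gave as many for rosoxacin against WTCPM (15, highest other 2), against control (91, highest other 1) and against dexamethasone (117, highest other 1). The same limits apply, so chance is less likely there but not excluded. For dexamethasone against control 3 splits gave as many (1, highest other 1), so chance cannot be excluded. For WTCPM against control (0 by limma with 141 at an unadjusted p under 0.05, highest other 1) and dexamethasone against WTCPM (0 with 148, highest other 1) all 35 splits reach the count of 0 by construction, so the splits say nothing about these. For the cytokine list after dust only the real split had a camera p as small (0.00177, smallest other 0.015). The list holds 3 measured genes and the limits above apply, so chance is less likely but not excluded. For the chemokine list after dust 5 splits had a camera p as small (0.00671, smallest other 7.28e-07). For cytokines with dexamethasone 3 did (0.00305, smallest other 8.76e-05), so chance cannot be excluded for either.

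Single mice far from the rest of their group are expected in about 1 in 20 groups, and 20 of 248 groups had one. In control 1 these were MSTRG.23017 at 2.88 (others 0.444 to 0.834), MSTRG.23451 at 47.6 (9.98 to 14.7), Ighv1-50 at 1.42 (0.341 to 0.492), Fam163b at 0.193 (0.423 to 0.461), Trbv16 at 1.22 (0.271 to 0.392) and Cxcl2 at 0.34 (0.125 to 0.157), and in control 4 Slc14a1 at 0.388 (0.29 to 0.305). In dexamethasone 4 they were MSTRG.23017 at 17.5 (58.8 to 64.5), MSTRG.17929 at 50.7 (17.1 to 21.2) and Fam163b at 0.817 (0.323 to 0.375), and in dexamethasone 2 Prr11 at 0.355 (0.3 to 0.307). In WTCPM mice they were Lep at 0.0471 in WTCPM 1 (others at 0), Il5ra at 0 in WTCPM 3 (0.135 to 0.158), and Itln1 at 0.0584 and Igkv13-84 at 0.533 in WTCPM 4 (others at 0). In rosoxacin mice they were Eprn at 0.0372 (others at 0) and Cxcr2 at 1.37 (0.651 to 0.737) in rosoxacin 1, Tdrd5 at 0.368 (0.186 to 0.217) in rosoxacin 2, and Ighv1-19 at 0.258 (others at 0) and Slc30a2 at 0.129 (0.177 to 0.184) in rosoxacin 4.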

How the results depend on the processing

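The library number as a covariate, the fits without 3 libraries, the fits without the 10 most abundant loci and the annotated genes were chosen after seeing the data, as were median-of-ratios scaling and log2(FPKM + 1) for named genes, and the other settings were planned. None of the 28 passing gene comparisons changed sign. Among those not passing, the sign changed in at least 1 setting or fit without 1 mouse for Cxcr2, Spdef, Tlr9, Tlr6, Gdf15 and Mmp13 (WTCPM against control), Saa1, C3ar1, Prox1, Il12b, Slc30a2 and Gdf15 (rosoxacin against WTCPM) and Cxcl1 (dexamethasone against WTCPM). What depth limits is unknown, since read counts are not given in the sources used here, and the cause was not tested for shifts between settings. Counts are of features past the threshold.

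For WTCPM against control (7 as deposited) the count was 12 with TPM, 3 with no filter, 4 with the second lane only, 35 with all 32 libraries and the mouse as a random effect, 2 with transcripts instead of loci, 3 with the most abundant transcript per locus, 2 with only the 2 groups compared, 56 with array quality weights, 285 with the first residual principal component as covariate, 32 at an unadjusted p and at least 2-fold, 4 with library number, 12 without the 3 libraries with the highest totals, 11 without the 10 most abundant loci and 0 among annotated genes by limma, where 141 had an unadjusted p under 0.05. Without 1 mouse it ranged from 4 (without control 3, WTCPM 2 or WTCPM 4) to 12 (without control 1).

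For rosoxacin against WTCPM (5940) the count was 10385 with TPM, 3286 with median-of-ratios scaling (1752 risen and 1534 fallen, against 88.9% fallen as deposited), 3948 with quantile normalisation, 3227 with transcripts, 3583 with the most abundant transcript, 9021 with the residual principal component, 267 at an adjusted p and at least 2-fold, 308 at an unadjusted p and at least 2-fold, and 15 among annotated genes. Without 1 mouse it ranged from 4693 to 7339. For rosoxacin against control (6443) it was 4216 with transcripts, 4219 with the most abundant transcript, 4183 with only the 2 groups, 518 and 533 with the 2-fold thresholds on adjusted and unadjusted p, 718 with library number and 91 among annotated genes, and 5317 to 6918 without 1 mouse. For rosoxacin against dexamethasone (7722) it was 745 and 751 with those 2-fold thresholds, 3396 with library number and 117 among annotated genes, and 6331 to 8979 without 1 mouse.

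For dexamethasone against WTCPM (0 by limma, 925 at an unadjusted p under 0.05) the count was 9 with the mouse as a random effect, 1 with transcripts, 1 with only the 2 groups, 687 with array quality weights, 101 with the residual principal component and 12 at an unadjusted p and at least 2-fold, and 0 to 0 without 1 mouse. For dexamethasone against control (2) it was 6 with quantile normalisation, 4 with a pseudocount of 0.1, 8 with no filter, 7 with a mean FPKM of at least 5, 4 with the first lane only, 62 with the random effect, 1 with the most abundant transcript, 633 with array quality weights, 113 with the residual principal component, 38 at an unadjusted p and at least 2-fold, 4 with library number and 1 among annotated genes. Without 1 mouse it ranged from 2 to 9 (9 without dexamethasone 4, 8 without rosoxacin 1, 4 without rosoxacin 2).

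Pairing was examined on residuals, which are the log2(FPKM + 1) values left after the group means were taken out. Residuals of mice with the same number in different groups had a mean r of 0.102, against -0.0283 for other numbers. Same-number pairs ranged from -0.467 to 0.737, with 10 of 24 above 0.1, and 10 mice matched best with their own number. The pairs control 1 with dexamethasone 1 (0.737) and control 4 with dexamethasone 4 (0.681) also have close library numbers (23 and 22, 7 and 9). Pairing by number is therefore not excluded, and these values cannot tell it from library number. With a replicate block the count was 12 for WTCPM against control and 4 for dexamethasone against control, and Lep passed for WTCPM against control (adjusted p = 0.0285, over settings up to 0.375). With the replicate block 5 calls were lost: Itln1 (rosoxacin against WTCPM, adjusted p = 0.0642, settings 0.0225 to 0.0948), Saa1 (rosoxacin against control, 0.0615, settings 0.0398 to 0.282), Asprv1 (dexamethasone against control, 0.0883, settings 0.0171 to 0.117), and Ttll8 (0.0533, settings 0.0315 to 0.808) and Igkv13-84 (0.0558, settings 0.0558 to 0.573) for rosoxacin against dexamethasone. With the WTCPM mice split 2 and 2 the correlation for dexamethasone was -0.27 instead of -0.563.

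MSTRG.23451 was lost with median-of-ratios scaling (adjusted p = 0.0958), no filter (0.14), the second lane (0.0562), the most abundant transcript (0.0925) and library number (0.104), over a range of 1.95e-05 to 0.152. Its log2 change ranged from -2.52 to -1.76 over the settings. Of 28 passing gene comparisons, 25 were lost with library number, 14 with quantile normalisation, 10 with log2(FPKM + 1) and 4 with median-of-ratios scaling, and 2 passed in every setting.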

Other observations

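The list of cell division genes was added after single genes had been seen, its genes not seen before were tested separately, and the test of variable segments was chosen only after the result was seen. Genes of cell division had higher means in dust-exposed lungs. All 10 members that had not been seen before were higher after dust, with a median of 0.42 on the log2 scale (camera p = 0.00165 with an estimated correlation, from limma). Examples from these, in mean FPKM of WTCPM against control, are Mybl1 (0.604 against 0.355), Ercc6l (0.501 against 0.333), Polq, a DNA polymerase (0.481 against 0.295), and Cenpw, a centromere protein (0.18 against 0.097), and 0 single genes passed limma's test after dust. Against control the unseen genes had a median of 0.26 with rosoxacin and 0.39 with dexamethasone, but the 3 comparisons share the control mice, so these are not independent of the first. Of the 35 splits only the real one had a camera p as small, with the smallest other at 0.0231. That is the smallest share such splits can show, so chance is less likely but not excluded. With library number as a covariate the median of the unseen genes was 0.38 after dust and 0.07 for rosoxacin against control. Whether more cells divide was not tested.

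Variable segments of antigen receptors had lower means in exposed lungs. Of 69 measured segments 60 were lower after dust (median -0.82), 64 with rosoxacin (median -1.13) and 55 with dexamethasone (median -0.53), each against the same 4 control mice, of which control 1 lay far above the others for Ighv1-50 and Trbv16. Of the 5 adipocyte genes, 1 of them seen before, 5 were lower after dust, 5 with rosoxacin and 4 with dexamethasone (medians -0.66, -0.64 and -0.60). Lower means are thus not limited to the segments, but the adipocyte list was itself added after the data were seen. Against control, the medians of all 2749 annotated genes were 0.03 after dust, -0.11 with rosoxacin and 0.02 with dexamethasone. Camera with an estimated correlation gave p = 0.0265 from limma after dust, 0.107 with rosoxacin and 0.0819 with dexamethasone, and a difference between the groups was not tested. For the 17 T cell receptor segments among them it gave 0.00138 (13 lower, median -0.61), 0.00989 (15 lower, median -0.97) and 0.0157 (13 lower, median -0.41), and with library number as a covariate 0.00902, 0.15 and 0.0173. For the 52 immunoglobulin segments it gave 0.0566, 0.18 and 0.127. Of the 35 splits 3 had a p as small after dust (smallest other 0.0156), so chance cannot be excluded. Shared reads between near-identical segments limit these values, and the source of the difference was not tested.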
